A study of Mus musculus with 7 samples.

How the data were processed

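Bulk RNA sequencing was done on liver from C57BL/6 mice kept on a Western diet for 30 weeks. Per the labels, the livers were flash frozen, RNA was extracted with Trizol and libraries were made with an Illumina protocol. The labels put 4 libraries in a group with high total bile acids (H-TBA) and 3 in a group with low total bile acids (L-TBA). The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries.

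The authors deposited raw counts per Ensembl gene, as whole numbers, with no normalization. The submitters' processing notes name CASAVA, TopHat2 2.0.11, DESeq2 1.18.1 and the mouse build mm9, without saying which step each served. The counting tool, its strand setting and the annotation release are not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies may therefore share counts, and values for members of the Cyp2c, Mup and Gsta families and for mitochondrial genes with nuclear copies are uncertain in that respect. Gene symbols came from a GENCODE table matched on the Ensembl identifier, and 32897 of the 37620 identifiers had a symbol. The reference annotation used for names belongs to another build than mm9, so no coordinates are given.

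Total counts ran from 9996990 to 12152613 per library. Genes were kept with the edgeR function filterByExpr (minimum count 10, minimum total count 15), which left 15249 of the 23697 genes with at least 1 count. Library sizes were scaled by TMM, and H-TBA was compared with L-TBA by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are H-TBA over L-TBA. Standard errors were derived from the fitted fold change and the quasi-likelihood F statistic. The common biological coefficient of variation was 0.125. Levels are TMM-scaled CPM, given as mean ± SD. For genes with 1 to 3 counts in a group, the ratio of summed counts per scaled library size is given with an exact 95% Clopper-Pearson interval.

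Before the data were examined, 47 gene lists were fixed, and the 45 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 45 lists. Camera was run again with the correlation estimated for each list, and fry was run on the same values. The named genes followed a rule that was also fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among genes past the threshold with a mean log2 CPM of at least 0, groups that did not overlap and an ordinary symbol; up to 3 members per list with the smallest adjusted p; and 20 bile acid, zonation, iron, tumour and fibrosis genes whatever their result. A gene that the rule selects is not reported here. Unless an alternative or a range over alternatives is named, every adjusted p given for a gene is from the edgeR test and every adjusted p given for a list is from camera. Ranges of adjusted p over the alternatives leave out the replicate block for genes and include it for lists.

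The edgeR and camera steps were tested on simulated counts for the 15249 tested genes, with the measured means, dispersions and library sizes and 200 changed genes. The comparison of 4 with 3 libraries recovered 74.0% of 2-fold changes and 95.0% of 4-fold changes, and 7.65% of the calls were genes that had not been changed. Of 10 shifted lists 10 were called, and of 40 unshifted lists 0 were called by camera. The simulated genes varied independently, which real genes do not. The 200 changed genes were split evenly between rises and falls, while 3638 genes were called in the data. These shares therefore do not carry over directly to the data.

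The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, DESeq2 size factors, library totals, leaving out the 20 most abundant genes, no filter, a stricter filter, a robust fit, the replicate number as a block, 1 surrogate variable from sva 3.50.0, other thresholds, and leaving out each library in turn. Offsets for gene length and for GC content and a fit to longer genes (at least 1000 bp of exon) were added after the fall of short genes had been seen. Lengths and GC came from GENCODE gene models and covered 96.3% of the tested genes. Within groups, the smallest chi-square per degree of freedom between libraries was 5.66, so none was deposited again under another name. Figures were drawn with matplotlib 3.10.9.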

Results

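Gene expression was measured in whole liver from C57BL/6 mice that had eaten a Western diet, rich in fat and sugar, for 30 weeks. The mice differed in their bile acids: 4 libraries came from the high total bile acid group (H-TBA) and 3 from the low group (L-TBA). The H-TBA libraries held 10959904, 9996990, 11071314 and 11488951 counts and the L-TBA libraries 12152613, 11660694 and 10973114. All 7 libraries had Y-linked Ddx3y at 708 to 882 counts and Xist at 1 to 6 counts. Spearman correlations between libraries lay between 0.981 and 0.992 within H-TBA, between 0.988 and 0.991 within L-TBA and between 0.955 and 0.981 across the groups. The first principal component held 64.7% of the variance and separated the groups. On it the L-TBA libraries lay between 36.8 and 45.2, H-TBA 2 to 4 between -43.5 and -34.6, and H-TBA 1 nearer to L-TBA at -10.7. The comparison asked how the liver transcriptome differs between mice with high and low bile acids on a diet that produces fatty liver disease.

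Livers of the H-TBA group had more transcript of bile duct marker genes and less from genes of the pericentral zone of the lobule, of fat storage and of fatty acid oxidation. The calls of these lists were lost with an estimated correlation (adjusted p = 0.469 for fat storage and adjusted p = 0.642 for the others). Krt19, a keratin of bile duct cells, rose from 6.04 ± 1.81 CPM (SD, n = 3) in L-TBA to 49.6 ± 17.9 CPM (SD, n = 4) in H-TBA. Glul, the glutamine synthetase of hepatocytes around the central vein, fell from 1622 ± 109 to 419.9 ± 158 CPM. Sds, a serine dehydratase of the periportal zone, rose from 104 ± 19.5 to 413 ± 83.1 CPM. Cidea, a lipid droplet protein, fell from 55.9 ± 31.3 to 2.61 ± 0.765 CPM.

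Of the 15249 genes tested, 2003 were higher and 1635 lower in H-TBA by edgeR's quasi-likelihood test at an adjusted p of 0.05, which is 23.9% of the genes. At least 2-fold changes were found for 1002 higher and 294 lower genes. In 33.5% of tested genes the libraries of the groups did not overlap, against 5.71% by chance. Higher genes made up 55.1% of the calls, and 78.9% (3117 higher, 832 lower) when libraries were scaled by their totals, a scaling that moved the median log2 fold change from 0.00 to 0.16. Without L-TBA replicate 1 the count of lower genes was 1035.

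**Figure D1:**
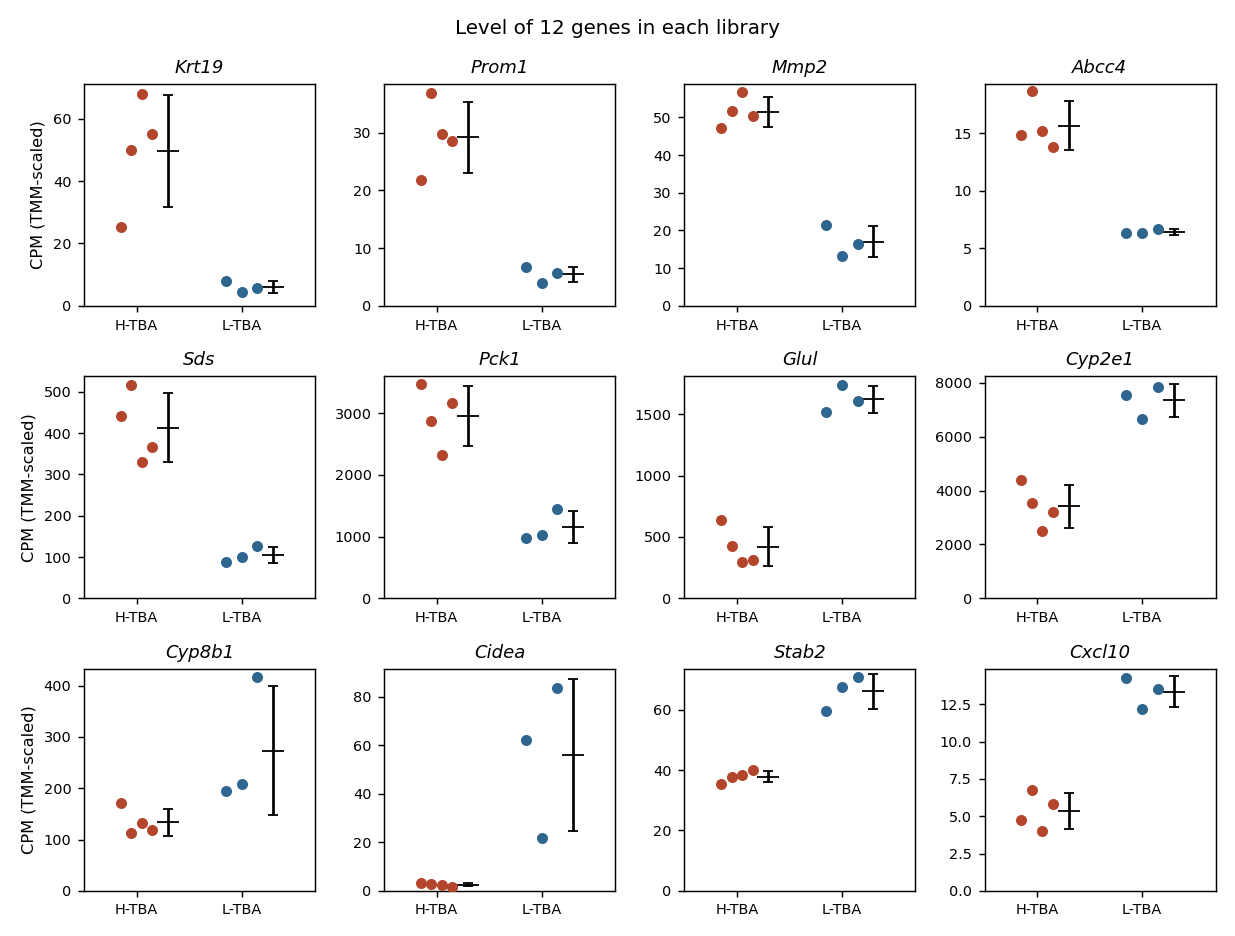
Level of 12 genes in each library. The vertical axes give TMM-scaled CPM from 0, each point is a library, and the bar beside the points is the mean with the SD (H-TBA n = 4, L-TBA n = 3); all 4 H-TBA libraries lie on one side of all 3 L-TBA libraries in each panel.

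The largest rises by the fixed rule included Slc4a9 (ENSMUSG00000024485), an anion exchanger, which rose from 0.0864 ± 0.15 to 2.70 ± 0.50 CPM (adjusted p = 0.00041). It had 122 counts over the H-TBA libraries and 3 in L-TBA, all in L-TBA 1, a ratio of 29.2 after scaling by library size (95% Clopper-Pearson interval 9.75 to 143, for counting error only). Cpxm2 (ENSMUSG00000030862), a secreted carboxypeptidase-like protein, rose from 0.391 ± 0.185 to 9.84 ± 1.84 CPM, a log2 fold change of 4.60 ± 0.31 (SE) with an adjusted p of 2.53e-05. Gabrp (ENSMUSG00000020159), a GABA receptor subunit of epithelia, rose by 3.89 ± 0.58 on the log2 scale to 6.01 ± 3.15 CPM. Cldn11, Ano9, Fam196b and Rnf208 rose and reached between 1.45 and 3.05 CPM. Cldn11 had 2 L-TBA counts and Fam196b 3, each in a single library, at ratios of 24.7 (6.60 to 208) and 15.5 (5.09 to 77.3). The log2 fold change was 4.14 for Ano9 and 3.79 for Rnf208, and that of Rnf208 was 5.72 without L-TBA replicate 1. Cyp2b10, a drug-metabolising enzyme induced through the receptor CAR, passed at 4.33 ± 1.35 with an adjusted p of 0.0351. That value rested mostly on H-TBA 2: without H-TBA replicate 2 the log2 fold change was 2.61. The Cyp2b10 call was lost without L-TBA replicate 1, 2 or 3 (adjusted p = 0.105, 0.0631 and 0.0991) and with the robust fit. Its adjusted p ran from 0.00471 to 0.134 over the alternatives.

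The largest falls by the same rule were Cidea (ENSMUSG00000024526; log2 fold change -4.43 ± 0.42, adjusted p = 0.000116), the collectin Colec10 (ENSMUSG00000038591; -4.26 ± 0.41) and the mitochondrially encoded mt-Atp8 (ENSMUSG00000064356; -4.07 ± 0.19, adjusted p = 2.41e-06). Colec10 went from 9.89 ± 3.05 to 0.505 ± 0.42 CPM. For mt-Atp8, its neighbour mt-Atp6 on the same mRNA did not fall alike, so the fall of mt-Atp8 need not be one of transcript. Pnldc1, Igf2bp2 and Adgrv1 fell, at -3.21, -3.05 and -2.89 on the log2 scale. Igf2bp2 encodes an RNA-binding protein of the fetal liver, and it went from 8.07 ± 2.35 to 0.949 ± 0.525 CPM. Folh1 and Esrrg, a nuclear receptor, fell, at -2.90 and -2.80, from levels of 1.72 and 3.75 CPM.

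Bile acid synthesis genes fell as a group by camera, and fry did not call them (adjusted p = 0.13). Of 18 tested members 5 fell and 0 rose, with 5 lower adjusted over the list alone (camera adjusted p = 0.00517; adjusted p = 0.642 with an estimated correlation). Without H-TBA replicate 1, 10 members fell, and 3 fell without H-TBA replicate 2 or 4 or L-TBA replicate 2 or 3. Library totals gave 2 higher and 3 lower members, with the median moving from -0.28 to -0.13, and limma-voom 0 and 8. Cyp8b1, the sterol 12-alpha-hydroxylase that sets the share of cholic acid, fell from 273 ± 125 to 134 ± 26.1 CPM (log2 fold change -1.03 ± 0.24, adjusted p = 0.0101; -0.59 without L-TBA replicate 3). Akr1c6 and the cholesterol 24-hydroxylase Cyp46a1 fell, at -0.63 and -1.38 on the log2 scale. The calls of Cyp8b1 and Akr1c6 were lost with the replicate block. Cyp7a1, the rate-limiting enzyme of the classic pathway, was at -0.48 ± 0.19 and did not pass (adjusted p = 0.0873, with 0.00583 without H-TBA replicate 1 and 0.0413 without L-TBA replicate 1, in a range from 0.00583 to 0.263 over the alternatives). Cyp27a1 and Cyp7b1, at -0.24 ± 0.14 and 0.25 ± 0.26, did not pass; without H-TBA replicate 1, Cyp27a1 passed.

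Transporters of bile acids and sterols moved both ways. Of 18 tested members 4 rose and 4 fell, the same numbers adjusted over the list alone, and the list did not pass camera (adjusted p = 0.808). Of the 4 that fell, the count was 2 without H-TBA replicate 2 or 3 or L-TBA replicate 3 and 1 without L-TBA replicate 1; library totals gave 4 higher and 2 lower. Abcc4, an exporter to the blood side of the hepatocyte, rose from 6.43 ± 0.241 to 15.6 ± 2.12 CPM (log2 fold change 1.28 ± 0.14, adjusted p = 0.000241). The sterol exporter subunit Abcg5 rose by 0.94 ± 0.13 and the organic anion transporter Slco1a4 by 0.82 ± 0.12. Slc10a1, the main sodium-dependent uptake carrier for conjugated bile acids, passed at -0.78 ± 0.25 (adjusted p = 0.0409) with overlapping groups. The Slc10a1 call was lost without H-TBA replicate 2, 3 or 4 and without L-TBA replicate 1 or 3 (adjusted p = 0.0926, 0.088, 0.116, 0.0873 and 0.161), in a range from 0.000316 to 0.161 over the alternatives. DESeq2, library totals, the robust fit and the replicate block lost that call as well. The canalicular bile salt export pump Abcb11 was at -0.07 ± 0.16 and the uptake carrier Slco1a1 at -1.13 ± 0.70, and neither passed (adjusted p = 0.783 and 0.272).

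Among 15 receptors and co-receptors for bile acids and xenobiotics, 2 rose and 3 fell, the same numbers adjusted over the list alone, and the list did not pass (adjusted p = 0.18); 1 rose without any 1 library except H-TBA replicate 2 or L-TBA replicate 2. With the GC offset the list passed (adjusted p = 0.0461, in a range from 0.0461 to 0.384). Nr1i3, which encodes CAR, fell from 255 ± 30.7 to 105 ± 19.1 CPM (log2 fold change -1.28 ± 0.14). Nr1h4, which encodes the bile acid receptor FXR, fell by 0.71 ± 0.14 (adjusted p = 0.0048), and S1pr2, a receptor for conjugated bile acids, fell by 0.63 ± 0.11. Fgfr4, the hepatic receptor for FGF15, rose by 0.53 ± 0.11. Nr0b2, the FXR target SHP, was at 0.13 ± 0.26 and did not pass (adjusted p = 0.747). In the list of detoxifying enzymes, 4 of 26 rose and 7 fell, with 4 and 8 adjusted over the list alone (camera adjusted p = 0.186), and 2 rose without L-TBA replicate 1. That list passed as lower without H-TBA replicate 1 (adjusted p = 0.0473) and with library totals (0.0266, with 8 higher and 6 lower members), in a range from 0.0266 to 0.539. Cyp2c37, Cyp2c38 and the bilirubin glucuronosyltransferase Ugt1a1 fell, at -1.68, -1.47 and -0.98 on the log2 scale, and Cyp3a11, a target of the receptor PXR, rose by 0.52 ± 0.13 (adjusted p = 0.0163). The Cyp3a11 call was lost without H-TBA replicate 2 or L-TBA replicate 1 (adjusted p = 0.0561 and 0.0976, in a range from 0.000232 to 0.0976). The replicate block lost that call as well.

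Hepatocyte genes of the lobule's zones moved in opposite directions. Of 30 pericentral genes 17 fell and 0 rose, with 19 lower and 2 higher adjusted over the list alone (camera adjusted p = 1.66e-06; adjusted p = 0.642 with an estimated correlation). Glul had a log2 fold change of -1.95 ± 0.23 (adjusted p = 0.0003), the ethanol-oxidising Cyp2e1 fell from 7354 ± 623 to 3413 ± 785 CPM (-1.11 ± 0.17) and the fatty aldehyde dehydrogenase Aldh3a2 fell by 0.83 ± 0.11. Of 33 periportal genes 15 rose and 6 fell, with 15 and 7 adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.653 with an estimated correlation). The periportal call was lost without H-TBA replicate 1 or L-TBA replicate 2 (adjusted p = 0.145 and 0.0546, in a range from 6.96e-06 to 0.145), and 3, 2 and 3 periportal genes fell without H-TBA replicate 3, H-TBA replicate 4 and L-TBA replicate 2, and 3 with library totals. Fry did not call the periportal list (adjusted p = 0.0503). The glutaminase Gls2 and tyrosine aminotransferase Tat rose by 1.25 ± 0.14 and 1.42 ± 0.16.

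Genes of the urea cycle and amino acid breakdown rose: 18 of 31 were higher and 4 lower, with 19 and 4 adjusted over the list alone (camera adjusted p = 6.76e-05; adjusted p = 0.642 with an estimated correlation). Of the urea cycle list, 2 members fell without H-TBA replicate 2 or 4 or L-TBA replicate 1 or 3, and also with library totals. Of the 15 periportal genes that rose, 8 are also in this list. Sds and its paralog Sdsl rose by 1.99 ± 0.17 and 1.37 ± 0.14, and the aspartate aminotransferase Got1 from 112 ± 34.9 to 450.3 ± 56.9 CPM (log2 fold change 2.01 ± 0.19, adjusted p = 0.000114). In glycolysis and gluconeogenesis 6 of 28 genes rose and 6 fell, with 7 and 9 adjusted over the list alone, and the list did not pass (adjusted p = 0.406); 10 fell without H-TBA replicate 1, and library totals gave 8 higher and 5 lower. Pck1, which encodes the phosphoenolpyruvate carboxykinase of gluconeogenesis, rose by 1.36 ± 0.18 to 2962 ± 486 CPM, the platelet-type phosphofructokinase gene Pfkp rose by 0.96 ± 0.16, and the hexokinase gene Hk2 fell by 1.73 ± 0.19.

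Lipid genes fell in 4 fixed lists by camera, and fry did not call the synthesis list (adjusted p = 0.0684). Fatty acid oxidation and ketogenesis had 22 lower and 1 higher of 34 members (23 and 1 adjusted over the list alone; camera adjusted p = 1e-07), and lipid droplet and fat storage 13 lower and 1 higher of 19 (13 and 1 adjusted over the list alone; 3.55e-06). Lipoprotein genes had 13 lower and 1 higher of 20 (13 and 1 adjusted over the list alone; 0.000183), and fatty acid and triglyceride synthesis 11 lower and 2 higher of 26 (15 and 2 adjusted over the list alone; 0.000333). With an estimated correlation no call held: adjusted p = 0.642 for oxidation, lipoprotein and synthesis and adjusted p = 0.469 for lipid droplets. Without H-TBA replicate 1, 17 synthesis genes fell. Without L-TBA replicate 2 or 3, 14 oxidation genes fell, with library totals 13, and 8 lipoprotein genes fell without any 1 library except H-TBA replicate 1 or L-TBA replicate 2. Vnn1 and Pex11a, targets of the receptor PPAR-alpha, fell, at -1.23 ± 0.11 and -1.27 ± 0.14, and the hormone gene Fgf21 fell by 0.92 ± 0.13. Mogat1, an acyltransferase of fatty liver, fell by 1.80 ± 0.23, and Aacs, an acetoacetyl-CoA synthetase, fell by 1.39 ± 0.17. Lpl, the lipoprotein lipase, rose by 0.67 ± 0.09, against the lipoprotein list. Pparg, a receptor that drives fat storage, and the triglyceride synthesis genes Dgat2 and Gpam also fell, at -0.66 ± 0.09, -0.67 ± 0.12 and -0.52 ± 0.09. Among 26 genes of cholesterol synthesis and uptake, 4 fell and 0 rose, also adjusted over the list alone, and the list did not pass (adjusted p = 0.143); 7 fell without H-TBA replicate 1, and 2 without any other 1 library except H-TBA replicate 3. Library totals turned its split to 5 higher and 1 lower, with the median moving from -0.12 to 0.03. Sc5d fell by 0.83 ± 0.11. Soat2 passed at -0.33, and its call was lost without L-TBA replicate 1 or 2 and with library totals (adjusted p = 0.086, 0.0685 and 0.172).

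**Figure D2:**
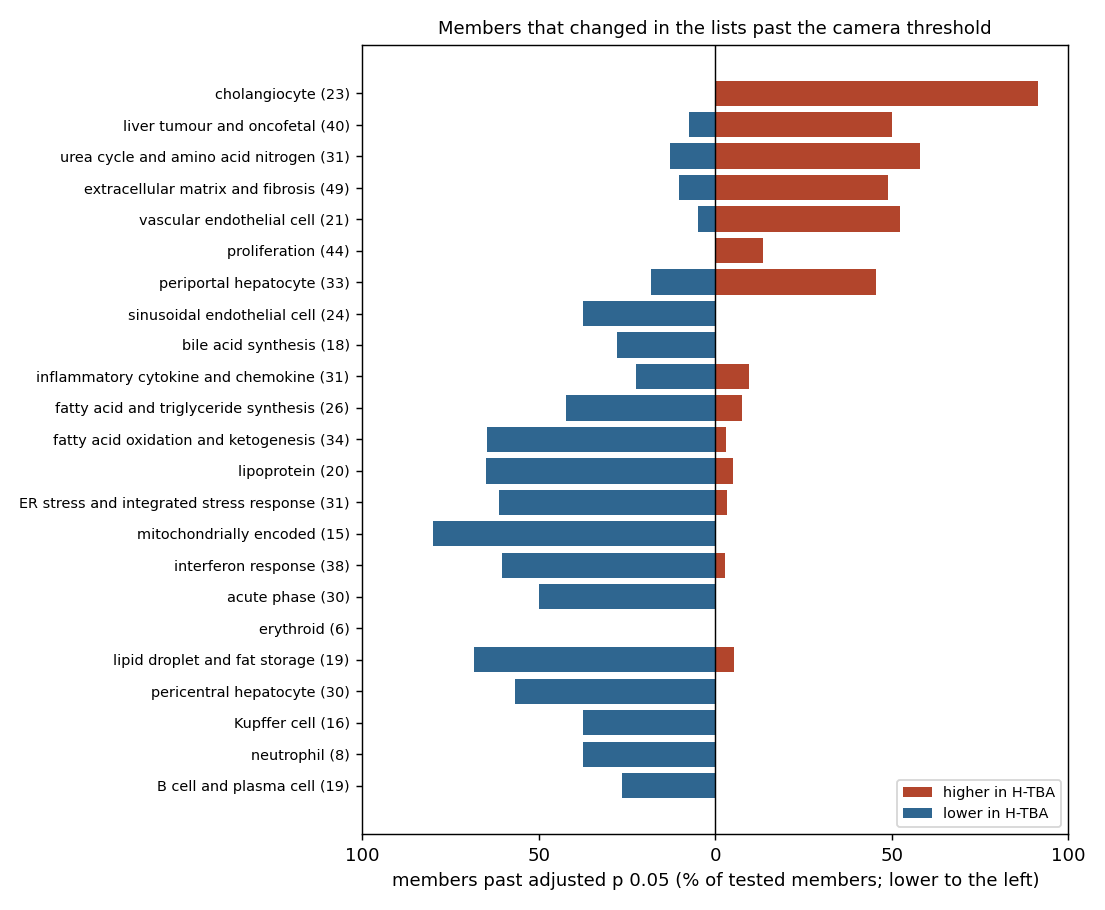
Share of tested members past an adjusted p of 0.05 in each of the 23 lists past the camera threshold. Bars to the right give the percent of members higher in H-TBA and bars to the left the percent lower, with the number of tested members in parentheses; cholangiocyte markers stand at the top, with 21 of 23 members higher and 0 lower.

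Markers of bile duct cells (cholangiocytes) rose almost throughout. Of 23 tested members 21 rose and 0 fell, also adjusted over the list alone, and the median log2 fold change was 1.91 (camera adjusted p = 2.26e-11; adjusted p = 0.642 with an estimated correlation). Krt19 had a log2 fold change of 3.03 ± 0.32 (adjusted p = 0.000208), the epithelial transcription factor Ehf 2.29 ± 0.22 and the RNA-binding protein gene Bicc1 1.74 ± 0.17. In the list of liver tumour and oncofetal genes 20 of 40 rose and 3 fell, with 21 and 3 adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.642 with an estimated correlation). Without L-TBA replicate 1 or 3, 13 rose, and without L-TBA replicate 3, 5 fell. Of the 20 that rose, 6 are also in the bile duct list. Tff3, a secreted trefoil peptide of mucosal epithelia, rose by 3.64 ± 0.43, Prom1, a progenitor and duct cell surface protein, by 2.42 ± 0.21 and the oncofetal proteoglycan gene Gpc3 by 1.73 ± 0.35 to 2.27 ± 0.659 CPM. Igf2bp2, in the same list, fell. Afp, the fetal liver secretory protein used as a tumour marker, was at -0.31 ± 0.25 and did not pass (adjusted p = 0.4).

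Genes of the extracellular matrix rose, with 24 of 49 higher and 5 lower (25 and 7 adjusted over the list alone; camera adjusted p = 0.000371; adjusted p = 0.642 with an estimated correlation). Fry did not call the matrix list (adjusted p = 0.0853). The matrix protease gene Mmp2 rose from 17.0 ± 4.14 to 51.5 ± 3.95 CPM (log2 fold change 1.60 ± 0.14), the collagen cross-linking enzyme gene Loxl1 by 1.51 ± 0.14 and Timp2 by 1.39 ± 0.15. Col1a1, the main fibrillar collagen gene, was at 0.11 ± 0.28 with an adjusted p of 0.823, and at 0.67 with an adjusted p of 0.0208 without L-TBA replicate 1, in a range from 0.0208 to 0.978. Its sign turned without H-TBA replicate 3, L-TBA replicate 2 or L-TBA replicate 3, at -0.02, -0.12 and -0.11, and with the GC offset. Stellate cell and fibroblast markers had 8 higher and 3 lower of 21 (10 and 4 adjusted over the list alone) and did not pass (camera adjusted p = 0.143; 0.0448 with DESeq2, in a range from 0.0448 to 0.69). Pdgfra, a receptor of mesenchymal cells, rose by 1.40 ± 0.12, and Angptl6 fell by 1.86 ± 0.31.

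Endothelial markers moved apart by type. Of 21 markers of vascular endothelium 11 rose and 1 fell, with 13 and 1 adjusted over the list alone (camera adjusted p = 0.00162; adjusted p = 0.642 with an estimated correlation); Cd34, Emcn and Ephb4 rose by 1.82, 1.45 and 0.98 on the log2 scale. Of 24 markers of sinusoidal endothelium 9 fell and 0 rose, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00785; adjusted p = 0.642 with an estimated correlation). The scavenger receptor gene Stab2 fell from 66.1 ± 5.74 to 37.8 ± 1.85 CPM (log2 fold change -0.80 ± 0.08), and Lyve1 and Clec4g fell, at -1.29 ± 0.18 and -0.80 ± 0.12. The sinusoidal call was lost without H-TBA replicate 1 or L-TBA replicate 3 (adjusted p = 0.0515 and 0.0563, in a range from 6.89e-05 to 0.0563), and 5 sinusoidal markers fell without L-TBA replicate 1. With library totals 5 fell and 1 rose, and the median moved from -0.26 to -0.09. Fry did not call the sinusoidal list (adjusted p = 0.102).

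Interferon response and acute phase genes fell as lists by camera, and fry did not call the acute phase list (adjusted p = 0.0503). Interferon response genes had 23 lower and 1 higher of 38 (27 and 1 adjusted over the list alone; camera adjusted p = 7.03e-09), and acute phase genes 15 lower and 0 higher of 30 (18 and 0 adjusted over the list alone; 1.66e-06); both had adjusted p = 0.642 with an estimated correlation. The interferon-induced GTPase genes Gbp7 and Irgm1 and the signal transducer Stat2 fell, at -0.86, -0.81 and -0.63, as did the serum amyloid genes Apcs and Saa4, at -1.52 ± 0.14 and -1.34 ± 0.16, and the metalloreductase gene Steap4, at -1.53 ± 0.20. Without L-TBA replicate 2, 9 acute phase genes fell. Lcn2, an acute phase protein of injured liver, was at -0.63 ± 0.36 and did not pass (adjusted p = 0.227); without L-TBA replicate 3 it passed. Cytokine and chemokine genes had 7 lower and 3 higher of 31, the same numbers adjusted over the list alone (camera adjusted p = 0.0417; adjusted p = 0.642 with an estimated correlation). That call was lost in 11 of 18 alternatives, among them without H-TBA replicate 1 or 2 and without L-TBA replicate 2 or 3 (adjusted p = 0.324, 0.0757, 0.0548 and 0.0636, in a range from 0.00128 to 0.324), and 6 of its genes rose without H-TBA replicate 1. With library totals 6 rose and 6 fell, and the list passed as lower (adjusted p = 0.00128). Fry did not call it (adjusted p = 0.102). The chemokine genes Cxcl10, Cxcl1 and Ccl6 fell, at -1.33, -1.04 and -1.25.

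Markers of Kupffer cells, neutrophils and B cells fell as lists by camera, and fry did not call the Kupffer and B cell lists (adjusted p = 0.14 and 0.257). Kupffer cell markers had 6 lower and 0 higher of 16 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00763), neutrophil markers 3 lower and 0 higher of 8 (5 and 0 adjusted over the list alone; 0.00365) and B and plasma cell markers 5 lower and 0 higher of 19 (6 and 0 adjusted over the list alone; 0.00517). With an estimated correlation, adjusted p = 0.642 for Kupffer and B cells and adjusted p = 0.469 for neutrophils. Without L-TBA replicate 3 the Kupffer and B cell calls were lost (adjusted p = 0.149 and 0.601, in ranges from 0.000235 to 0.149 and from 2.74e-05 to 0.601). The count of B cell markers that fell was 3, 2, 3 and 1 without H-TBA replicates 1 to 4, 8 without L-TBA replicate 1, 1 without L-TBA replicate 3, 2 with library totals and 3 with limma-voom. The Kupffer cell genes Cd5l and Folr2 and the interleukin-18 inhibitor Il18bp fell, at -1.36 ± 0.18, -1.49 ± 0.26 and -0.80 ± 0.12. Only 8 of the 21 neutrophil list genes were tested, and Lcn2 among them is also in the acute phase list. The fall of that list therefore need not be one of neutrophils. The neutrophil chemokine receptor Cxcr2 fell by 0.73 ± 0.16. S100a8 and Fpr2 passed at -1.11 and -1.81, at most 1.73 CPM in either group; the S100a8 call was lost without H-TBA replicate 3 or 4 or L-TBA replicate 2 or 3 (adjusted p up to 0.121) and with DESeq2 (0.0748), and the Fpr2 call without H-TBA replicate 2 or 4 or L-TBA replicate 3 (up to 0.157). The B cell genes Derl3 and Bank1 passed at -1.49 and -1.56. The Derl3 call was lost without L-TBA replicate 3 (adjusted p = 0.0551), and that of Bank1 without H-TBA replicate 2 or 4 or L-TBA replicate 3 (up to 0.175, at -0.93 without L-TBA replicate 3) and with library totals (0.0546). Ighm passed at -2.69 ± 0.69 with 204 ± 251 CPM in L-TBA. Without L-TBA replicate 3 it was at -0.91 and did not pass, and the call was also lost without H-TBA replicate 2 or 4 (adjusted p = 0.121, 0.0558 and 0.0577, in a range from 0.000864 to 0.122). Limma-voom, the robust fit and the replicate block lost the Ighm call as well. Recruited macrophage markers had 6 higher and 9 lower of 31 (6 and 10 adjusted over the list alone; camera adjusted p = 0.195), or 6 and 5 with library totals. Mmp12 and the galectin gene Lgals3 fell, at -0.93 and -0.76, while Lpl rose. T cell markers had 2 higher and 1 lower of 27 (1 and 1 adjusted over the list alone; 0.286), with 5 higher without H-TBA replicate 1 and 1 without H-TBA replicate 3 or 4 or L-TBA replicate 1 or 3. Zap70, a kinase of T cell receptor signalling, rose by 1.48 ± 0.17 and Themis fell by 1.13 ± 0.22. Cxcr6 passed at 1.14, and its call was lost without any 1 library except H-TBA replicate 1 or 2 (adjusted p up to 0.142) and with DESeq2 (0.0555). Class II antigen presentation genes had 0 higher and 0 lower of 12 by edgeR, also adjusted over the list alone (0.67), with 1 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom; without H-TBA replicate 1, 3 class II genes rose. H2-DMb1, its member with the smallest p, was at -0.34 and did not pass (adjusted p = 0.104); it passed without L-TBA replicate 3 (0.0393) and with 1 surrogate variable (0.0266), in a range from 0.0266 to 0.469.

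Proliferation genes had 6 higher and 0 lower of 44, with 2 and 0 adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.642 with an estimated correlation), with 10 higher without H-TBA replicate 1, 2 without H-TBA replicate 2 or L-TBA replicate 1 and 3 without H-TBA replicate 3 or L-TBA replicate 2. DESeq2 gave 3 higher, and limma-voom and library totals 11 each. Fry did not call the proliferation list (adjusted p = 0.102). The cyclin genes Ccnb2 and Ccnd1 rose by 0.90 ± 0.17 and 0.84 ± 0.20. The Ccnd1 call was lost with the replicate block. Stmn1 passed at 0.64, and its call was lost without H-TBA replicate 2 or 3 or L-TBA replicate 1 or 2 (adjusted p up to 0.0815). Mki67, a marker of dividing cells, was at -0.03 ± 0.27 (adjusted p = 0.944), with either sign over the alternatives. Genes of endoplasmic reticulum stress fell, with 19 lower and 1 higher of 31 (22 and 1 adjusted over the list alone; camera adjusted p = 1.02e-06; adjusted p = 0.642 with an estimated correlation). The chaperone genes Calr and Hyou1 fell, at -0.88 ± 0.11 and -0.84 ± 0.11, and Ddit4, an inhibitor of mTORC1 signalling, rose by 0.95 ± 0.11.

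Iron genes had 7 higher and 4 lower of 27 (8 and 6 adjusted over the list alone) and did not pass camera (adjusted p = 0.718), with 2 lower without L-TBA replicate 2. Library totals gave 9 higher and 1 lower, and turned the median from -0.08 to 0.07. Hamp, which encodes the iron hormone hepcidin, rose from 211 ± 85.1 to 421 ± 90.8 CPM (1.99-fold, adjusted p = 0.0133), and its inducer Bmp6 rose by 1.35 ± 0.29. Smad7, an inhibitor of that signalling, rose by 0.60 ± 0.12, and the heme oxygenase gene Hmox1 fell by 0.78 ± 0.15. The Hamp call was lost with the replicate block. The glutathione and oxidative stress list had 9 higher and 7 lower of 28 (9 and 8 adjusted over the list alone; adjusted p = 0.536). Its lower members were 3 without H-TBA replicate 2 or 4 or L-TBA replicate 1 or 2, and 4 without H-TBA replicate 3. Library totals gave 11 higher and 3 lower, and moved the median from 0.00 to 0.15. The glutathione transferase gene Gsta2 was higher by 1.56 ± 0.15, the plasma peroxidase gene Gpx3 by 1.48 ± 0.13 and the epithelial peroxidase gene Gpx2 by 2.62 ± 0.31. Growth hormone and IGF genes had 6 higher and 3 lower of 21, the same numbers adjusted over the list alone (camera adjusted p = 0.39). Fry called this list as higher (adjusted p = 0.0173). Igfbp2 and Socs2 rose by 1.51 and 1.45, and the prolactin receptor gene Prlr fell by 1.22 ± 0.17.

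Mitochondrially encoded genes fell, with 12 lower and 0 higher of 15 (13 and 0 adjusted over the list alone; camera adjusted p = 6.03e-07; adjusted p = 0.642 with an estimated correlation). Without H-TBA replicate 4 or L-TBA replicate 3, 6 of them fell, and without L-TBA replicate 1, 7. The light-strand gene mt-Nd6 fell by 1.47 ± 0.28. The share of mitochondrially encoded genes among all counts was 5.17% to 6.39% in H-TBA and 7.09% to 7.72% in L-TBA. The shortest members fell most: mt-Atp8 was at 91 to 154 counts in H-TBA and 1684 to 1905 in L-TBA, while mt-Atp6, which lies on the same mRNA, was at -0.40 on the log2 scale and did not pass (adjusted p = 0.0651). It passed in 6 of the alternatives, among them DESeq2, limma-voom and, at -0.49, the fit without H-TBA replicate 1 (adjusted p = 0.0143, 0.0258 and 0.0174, in a range from 0.00569 to 0.192 over the alternatives). The fall of mt-Atp8 therefore need not be one of transcript. A difference in the libraries or their counting is a candidate for part of it. Nuclear genes with at most 300 bp of exon also lay lower, with 33 of 95 lower and 8 higher, and a length offset gave 1917 higher and 1618 lower genes over all. With an estimated correlation camera called 0 of the 45 lists (2 had an unadjusted p under 0.05), against 23 with the preset one (7 higher, 16 lower) and 13 by fry, and 3 of the 35 possible splits of the libraries gave 23 or more lists.

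**Figure D3:**
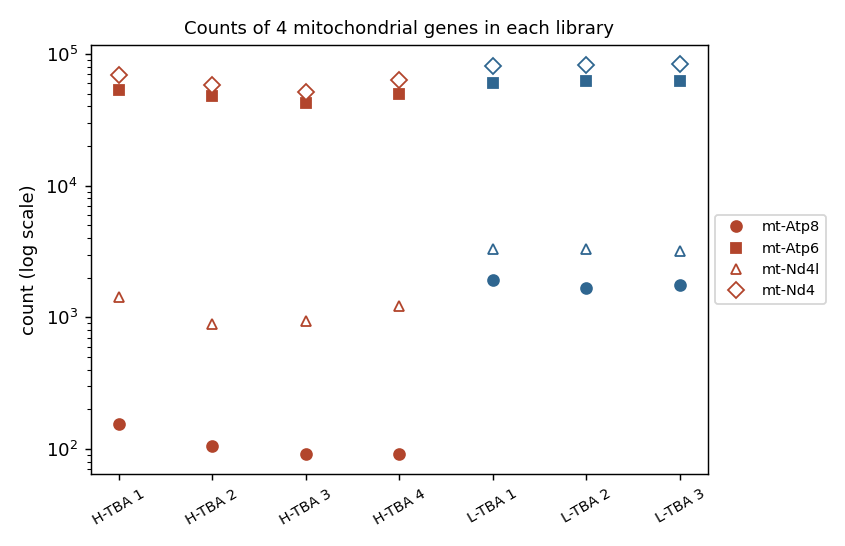
Counts of mt-Atp8, mt-Atp6, mt-Nd4l and mt-Nd4 in each library, on a log axis, with H-TBA libraries in red and L-TBA libraries in blue. The mt-Atp8 points fall from at least 1684 counts in L-TBA to at most 154 in H-TBA, while mt-Atp6 lies at 60404 to 62127 counts in L-TBA and 42097 to 53551 in H-TBA.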

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

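The tests of the hepatocyte share on cell type markers, of the shared mRNA and of short genes, and the length and GC offsets, were chosen after the results had been seen; that of the hepatocyte share against the other lists was the third one tried. Among 210 values looked at in the 4 H-TBA libraries, 10 had 1 library apart from the other 3 by more than Dixon's 95% critical share of the range, which chance gives in about 1 of 20.

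For Cyp2b10 the gap was 0.978 of the range, with H-TBA 2 highest at 3.42 log2 CPM. For Nr1h4 it was 0.964, with H-TBA 1 highest at 6.60 log2 CPM, and for the cyclin gene Ccnb2 0.868, with H-TBA 1 lowest at 2.31. For Esrrg it was 0.932 and for Fkbp5 0.923, with H-TBA 3 lowest in both, at -1.94 and 5.20 log2 CPM. For the phospholipid transfer protein gene Pltp it was 0.97 and for Hyou1 0.874, each with H-TBA 4 highest. For Lpl it was 0.871, with H-TBA 1 lowest, and for Prlr 0.857, with H-TBA 1 highest. For the mean level of the growth hormone and IGF list it was 0.837, with H-TBA 2 lowest.

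The first pattern is the fall of mt-Atp8 beside mt-Atp6. Less of their shared mRNA would leave the ratio of the counts alike, but the mean log2 ratio of mt-Atp8 to mt-Atp6 was lower by 3.70 in H-TBA (difference -3.70, SD 0.27 and 0.112 within groups), with no overlap, and that of mt-Nd4l to mt-Nd4 differed by -1.13. A loss of short genes in the H-TBA libraries or their counting is a candidate explanation for part of it: 95 nuclear genes with at most 300 bp of exon had a median log2 fold change 0.41 below longer genes of like expression (-0.408), lower than in all 10000 random draws. That shift is far smaller than the fall of mt-Atp8, which stayed at -3.89 with a length offset (-3.889), so a length trend shared with other genes is argued against as its whole cause. The labels give no library batch, so a biological difference in short nuclear transcripts between the groups stays open and untested. Such a difference could not lower mt-Atp8 against mt-Atp6, since both lie on the same mRNA. The ratio's difference of -3.70, with no overlap, argues against it for mt-Atp8. For the short nuclear genes, a technical difference between the groups cannot be told apart from a biological one.

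The second pattern is the rise of bile duct markers with a fall of Kupffer, sinusoidal endothelial and B cell markers. A lower hepatocyte share alone would raise markers of all other liver cell types alike, but the mean log2 level of bile duct markers rose against that of each of 9 other cell type lists, by 1.15 to 2.66, with no overlap between the groups. Of the 9 lists, 3 are the falling lists of the pattern, and the bile duct rise was known beforehand, so the comparison in part restates the pattern. The bile duct level also rose against the lists outside the pattern, such as vascular endothelial (1.15) and stellate markers (1.45). That argues against a lower hepatocyte share as the whole cause of the bile duct rise. What it adds beside the fall of the 3 lists stays open: their mean levels overlapped between the groups (0 of 3 apart), and without L-TBA replicate 3 they had 5, 6 and 1 lower and 1, 1 and 0 higher members, with medians of -0.14, -0.10 and -0.05. Gene length is argued against, since bile duct markers kept a median of 1.90 with a length offset, and a change in the number of bile duct cells or in their expression stays open.

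The third pattern is the fall of pericentral genes with a rise of periportal genes. Both belong to hepatocytes, so a lower hepatocyte share alone would lower both. The mean level of periportal genes was higher by 0.433 log2 CPM in H-TBA, with no overlap between the groups. That rise is part of the pattern and no separate test, and 8 of the 15 periportal genes that rose are in the urea cycle list. A lower hepatocyte share alone would not give the pattern, but whether it adds to the pericentral fall was not tested. With a length offset the pericentral median was -0.77, which argues against gene length. The bile acid group itself stays open as a biological explanation and was not tested further. The labels give no technical batch. The log2 ratio of mt-Atp8 to mt-Atp6 differed between the groups by -3.7 with no overlap, which less of their shared mRNA would not give. A technical difference that follows the groups is a candidate for that. How far it reaches the genes of this pattern cannot be weighed.

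Of the 35 splits of the 7 libraries into 4 and 3, only the real one gave 2003 higher genes (highest other 1272) and only the real one gave 1635 lower genes (highest other 1534). That is 1 of 35 each, the smallest share possible, so a random grouping of these libraries can be excluded at 0.05 for both counts. The labels do not say that the libraries are separate animals, and a technical difference that follows the groups would give the same outcome. The highest others set H-TBA 2, 3 and 4 against the rest, which places H-TBA 1 with L-TBA. For the number of lists past camera, 3 of the 35 splits gave as many as the real 23, with 24 the highest other, so chance cannot be excluded for that number. The other splits gave 7 to 24 lists, also where no gene was called.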

How the results depend on the processing

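The length and GC offsets and the fit to genes with at least 1000 bp of exon were chosen after seeing the data. Of the 23 lists called, 17 kept their call in all 18 camera alternatives with the preset correlation. Camera with that correlation also called 7 to 24 lists in the other splits of the libraries, so a kept call is no separate support. Over 159 named genes and their alternatives, 3006 of 3152 pairs kept direction and side of the threshold, 93 lost the call, 36 gained it and 17 turned sign. Counts of higher and lower genes were within 1.5 times the reported ones except as follows, and the cause was not tested except where the setting itself gives it. Library totals gave 3117 higher and 832 lower genes, a split of 78.9% higher, as the median moved to 0.16. At least 2-fold changes left 1002 and 294, by construction. The replicate block gave 1166 higher and 754 lower genes. It lost the calls of Cyp8b1, Akr1c6, Slc10a1, Cyp3a11, Hamp, Ccnd1, Ighm, Sp5 and Soat2. Those of Eif2s3y, Vsir, Nr4a1, Npas2, S100a8, Fpr2, Cxcr6, Derl3 and mt-Nd4 were lost with it as well. Same-numbered libraries deviated from their group means with correlations of -0.103, -0.0589 and -0.0627, which show no sign of pairing. With so few libraries this cannot exclude that the numbers pair them. Leaving out a library gave 1470 to 2429 higher genes, 1035 to 2123 lower genes and 18 to 23 lists. Camera with estimated correlations called 0 of 45 lists, and fry called 13, of which 12 were among the 23. The other fry call was the growth hormone and IGF list. Of the 23, fry did not call the lists of bile acid synthesis, fatty acid and triglyceride synthesis, periportal, acute phase and cytokine genes. It also did not call those of extracellular matrix, proliferation, sinusoidal endothelial, Kupffer, B cell and erythroid genes. Their fry adjusted p ran from 0.0503 to 0.257.

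Genes that turned sign were near 0 or had wide spread, and none had passed. Without 1 library in turn, Slco1a1 ran from -1.85 to 0.30 (positive without L-TBA replicate 3), Abcb11 from -0.22 to 0.044 (positive without H-TBA replicate 3 or, at 0.011, L-TBA replicate 2), Nr0b2 from -0.18 (without H-TBA replicate 1) to 0.32, Col1a1 from -0.12 to 0.67 and Mki67 from -0.31 to 0.40. Col1a1 was at -0.016 without H-TBA replicate 3 and at -0.12 and -0.11 without L-TBA replicates 2 and 3, and Mki67 at 0.086 and 0.40 without H-TBA replicate 1 and L-TBA replicate 3. Library totals put Abcb11 at 0.070, Alb at 0.012 and Mki67 at 0.14, limma-voom put Nr0b2 at -0.040 and Mki67 at 0.18, the GC offset put Col1a1 at -0.052 and Mki67 at 0.0049, and the replicate block put Mki67 at 0.012. For these the cause was not tested. At totals of 9996990 to 12152613 counts, the simulation recovered 74.0% of 2-fold changes, so smaller changes and low genes are the least certain.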

Other observations

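The tests of the glucocorticoid and Wnt lists were planned before the lists' values were seen. Those 2 lists and the hepatocyte list were made after the main comparison had been seen. Of the tested genes of the 2 lists, 5 of 12 and 9 of 10 were already in the fixed lists of that comparison. Sex-biased liver genes also moved within these libraries, all of male pattern. Female-biased genes had 12 higher and 9 lower of 40 (14 and 11 adjusted over the list alone; camera adjusted p = 0.87), and male-biased genes 3 higher and 7 lower of 30, also adjusted over the list alone (0.229). Without L-TBA replicate 1 the female-biased list had 7 higher and 5 lower. The male-biased list passed as lower without L-TBA replicate 2 (adjusted p = 0.0105), without H-TBA replicate 1 (0.0449) and with library totals (0.0272), while without L-TBA replicate 3 its adjusted p was 0.991 and its median turned from -0.16 to 0.18, in a range from 0.0105 to 0.991. Fmo2, a flavin monooxygenase gene higher in female liver, rose from 23.4 ± 0.706 to 73.3 ± 7.09 CPM, and Mup3, a urinary protein gene of male liver with near-identical copies, fell from 1300.8 ± 321 to 353 ± 136 CPM. Wfdc21 and Ces2e, of the male-biased list, fell, at -1.02 and -0.73. Of the female-biased list Lpl rose and Prlr fell. Erythroid genes had 0 higher and 0 lower of 6, with 4 lower adjusted over the list alone (camera adjusted p = 0.0471; adjusted p = 0.642 with an estimated correlation); 4 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 4, 4 fell without H-TBA replicate 1, Hbb-bt was at -0.67 and did not pass (adjusted p = 0.0543, passing at 0.00147 without H-TBA replicate 1 and 0.0478 without L-TBA replicate 1, in a range from 0.00147 to 0.196), and the list call was lost in 10 of 17 alternatives.

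Lists with no call were the following. Genes of p53, DNA damage and cell death had 2 higher and 6 lower of 28 (also adjusted over the list alone; camera adjusted p = 0.344; 4 and 5 with library totals), immediate early genes 4 and 2 of 22 (also adjusted over the list alone; 0.604; 0 to 2 higher without H-TBA replicate 3 or 4 or L-TBA replicate 1 or 2) and clock genes 2 and 2 of 21 (2 and 1 adjusted over the list alone; 0.577). Gdf15, Aen and Casp8 fell, at -1.36, -0.68 and -0.51, as did the stress factor Atf3 and the clock-controlled factor Hlf, at -0.77 and -0.98, while Tsc22d3 rose from 43.8 to 87.6 CPM. Nr4a1, Ier2 and Npas2 passed at 1.19, 0.54 and 1.23. Calls were lost for Nr4a1 without L-TBA replicate 1 or 3 (adjusted p = 0.0687 and 0.0676), for Ier2 without H-TBA replicate 3 or 4 or L-TBA replicate 1 or 2 (up to 0.0849) and with the GC offset (0.133), and for Npas2 without L-TBA replicate 1 (0.0643). Immune checkpoint genes had 1 higher and 1 lower of 12 (also adjusted over the list alone; 0.661). Cd274, which encodes PD-L1, fell by 0.87, and Vsir passed at 0.39 with a call that was lost without any 1 library except H-TBA replicate 1 or 2 (adjusted p up to 0.146) and with DESeq2 (0.058). NK cell genes had 0 and 0 of 7 by edgeR (also adjusted over the list alone; 0.716), with 1 at an unadjusted p under 0.05 and 1 called by DESeq2 and by limma-voom. Il18r1 was at 1.15 and did not pass (adjusted p = 0.0504); it passed without H-TBA replicate 1 (0.0236), with library totals (0.036) and in 4 other alternatives, in a range from 0.0236 to 0.147. Adipocyte genes had 1 and 2 of 6 (also adjusted over the list alone; 0.604), pancreas, gallbladder or gut genes 1 and 1 of 5 (also adjusted over the list alone; 0.661) and muscle or mesothelium genes 1 and 0 of 6 (3 and 0 adjusted over the list alone; 0.365). In these lists Cidec and Cfd fell, at -0.87 and -2.24, Vil1 rose by 2.14, Fabp2 fell by 0.90 and Msln rose by 2.49. The Cfd call was lost with a robust fit (adjusted p = 0.0696). The 4 tested sex chromosome genes had 1 lower, Eif2s3y at -0.37, whose call was lost without H-TBA replicate 2 or 4 or L-TBA replicate 2 or 3 (adjusted p up to 0.0981), with library totals (0.23) and with the GC offset (0.056). The 4 tested substrain genes had 0 higher and 0 lower by edgeR, with 2 at an unadjusted p under 0.05, 0 called by DESeq2 and 1 by limma-voom. Ide was at -0.25 (adjusted p = 0.0946) and passed without H-TBA replicate 1 (0.00528), with limma-voom (0.0238) and with 1 surrogate variable (0.0214), in a range from 0.00528 to 0.43.

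A hypothesis was that a stronger glucocorticoid signal may accompany the rise of amino acid breakdown genes such as Tat and Pck1. Of 12 receptor targets chosen without those genes, 4 rose adjusted over the list alone and 0 fell, with a median of 0.41 (camera p = 0.119; p = 0.43 with an estimated correlation). Fkbp5 rose by 0.76 ± 0.12 and Sgk1 by 0.61 ± 0.12, while Mt1 and Mt2 were at -0.48 and -0.64 and did not pass. Without L-TBA replicate 3 both passed (adjusted p = 0.02 and 0.0162, in ranges from 0.02 to 0.572 and from 0.0162 to 0.647). Since 4 lies between the bounds set for and against it, the hypothesis stays undecided, and 5 of the 12 are in other lists.

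Another hypothesis was that a weaker Wnt signal may accompany the fall of pericentral genes such as Glul. Of 10 tested Wnt targets outside metabolism, 3 fell and 2 rose adjusted over the list alone, with a median of -0.14 (camera p = 0.318; p = 0.345 with an estimated correlation). Tbx3, Sp5 and Rnf43 fell, at -1.17, -0.99 and -0.53, while Axin2 and Lgr5 were at -0.33 and -0.68 and did not pass. Without L-TBA replicate 1 the calls of Sp5 and Rnf43 were lost (adjusted p = 0.0768 and 0.0563, in ranges from 0.00783 to 0.0768 and from 0.00331 to 0.0563), that of Rnf43 also with library totals (0.0541), and without H-TBA replicate 1 Lgr5 passed at -1.03 (adjusted p = 0.0022, in a range from 0.0022 to 0.262). The replicate block also lost the Sp5 call. With 3 of 10 lower the outcome lies between the bounds set for and against the hypothesis and stays undecided. Of the 10, 9 are in other lists, and most are in the pericentral list itself, among them Tbx3, Sp5 and Rnf43. The test was therefore not independent of the pericentral fall. Hepatocyte secreted proteins, 15 genes made as a reference, had 1 higher and 2 lower and a median of -0.15 (camera p = 0.0261; p = 0.354 with an estimated correlation), with Alb at -0.14 ± 0.13, and at 0.01 with library totals.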
